A study of Homo sapiens with 6 samples.

How the data were processed

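Poly(A) RNA was sequenced from 6 libraries of 22RV1, an established human prostate cancer cell line that grows without androgen. Each of 3 groups had 2 libraries: cells stably expressing a hairpin against luciferase (shLuc, the control), against IMPA1 (shIMPA1) or against IMPDH2 (shIMPDH2). Per the labels' protocols, the cells grew in RPMI-1640 with fetal bovine serum. The labels name 1 stable line per group and do not say whether the 2 libraries of a group came from separate cultures or separate hairpins, so p-values measure only the spread between these libraries, which may be technical.

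Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned to GRCh38 with STAR 2.5.2b and counted with Subread 1.5.2. Per the labels' protocols, uniquely aligned reads within exons were counted per gene, with strand used only where the library preparation kept it. Whether it did, and which annotation release was used, are not given in the sources used here. Reads from overlapping or antisense genes therefore cannot be told apart with certainty. The deposited signal values are, per the file headers and the values themselves, read counts that the authors divided by 1 size factor per library. The deposited table also holds a log2 fold change column, a p-value column and an adjusted p-value column of the authors, for a comparison that its header does not name. These 3 columns entered no test here.

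The table listed 17811 genes by Ensembl identifier. Symbols came from a table of gene names for 16275 of them and from GENCODE release 29 for a further 97, and 1439 had no symbol. GENCODE release 29, on GRCh38, held 17750 of the identifiers, and coordinates are from it. Dividing each library's values by the value of 1 read gave whole numbers, within a tolerance of 0.05 reads, for 99.98% to 100% of the genes in each library. The recovered totals over the listed genes were 27405563 and 27773294 reads in shLuc, 26215122 and 27601249 in shIMPA1, and 20828900 and 22442454 in shIMPDH2. Size factors recomputed with DESeq2 or with edgeR's TMM moved no library by more than 0.012 on the log2 scale.

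The tests planned before the data were examined used edgeR on counts, with limma on log2(value + 1) where the file held normalized values. The file held normalized values, so limma gave the main results. Genes with a value of at least 10 in at least 2 libraries were kept, which left 17742 and removed 69. One limma model (version 3.58.1 in R 4.3.3) with a mean-variance trend covered all 6 libraries, with 1 coefficient per group, 3 residual degrees of freedom and no replicate term. Each pair of groups was compared, and Benjamini-Hochberg adjusted p-values under 0.05 were called. Fold changes are on the log2(value + 1) scale, which understates the change of genes with few reads. SE is the moderated standard error from limma. Where a group held no read of a gene, the fold is given as a lower bound from 3 reads over the group, and where it held 1 to 3 reads, as a ratio with a 95% counting interval. Such bounds and intervals cover counting error only. On simulated data with 200 changed genes, the test recovered 33.9%, 69.3% and 92.8% of 1.5-fold, 2-fold and 4-fold changes for shIMPA1 against shLuc. The same shares were 18.5%, 75.8% and 89.9% for shIMPDH2 against shLuc, and 25.0%, 72.9% and 96.5% between the knockdowns. Of 146, 134 and 130 calls in these simulations, 11, 10 and 11 were false. Between 3018 and 5361 genes were called in the data, far more than were simulated, so these shares need not hold there.

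The genes named were fixed by rule before the data were examined. They were IMPA1 and IMPDH2, then the 12 largest rises and the 12 largest falls against shLuc, 6 each way between the knockdowns, and 8 each way shared by both knockdowns, ranked by the smaller of the 2 changes. These had to have a symbol, a call, a mean of at least 2 CPM, and both libraries of one group above both of the other. Up to 4 members of each gene list with the smallest adjusted p were also named. The 5 genes each way that changed in opposite directions were a rule added after the data were seen, and any other gene is said to be chosen after its values were seen. Y-linked genes and XIST were left out. Some genes that met the rule are not reported here.

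A set of 33 gene lists was fixed at the same time, with 795 members of which 716 were tested. Lists were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. Camera with an estimated correlation and fry, which asks whether a list's own genes move one way, were run beside it. With an estimated correlation, no list passed in any comparison (1, 4 and 3 lists had an unadjusted p under 0.05 for shIMPA1, for shIMPDH2 and between the knockdowns), whereas fry called 16, 6 and 17. The lists fry called were in part not those camera called. In shIMPA1, fry called p53 targets (fry adjusted p = 0.00892) and hypoxia genes (0.00450), which camera did not, and missed G2/M genes (0.150), which camera called. The test with an estimated correlation rests on the 3 residual degrees of freedom, so it had little power after adjustment. Mesenchymal genes in shIMPDH2 had an estimated correlation of 0.0042, below the preset. Their unadjusted camera p was still 3.00e-06 with the preset and 0.0163 with the estimate. For a list with so low an estimate, a failure of that test therefore does not by itself show that correlation between genes made a call. Estimates were also low for androgen response (-0.022), histone (-0.052) and heat shock genes (0.080). They lay far above the preset for G2/M (0.963), mitochondrially encoded (0.855), G1/S (0.716), ribosomal (0.645), cholesterol (0.544), endoplasmic reticulum (0.470) and ATF4 genes (0.339). For these lists the camera p with the preset may be far too small. Every list call given is one made with the preset correlation. Counts within a list use the adjustment over all genes unless the words "adjusted over the list alone" appear. List medians did not move when genes without reads were set to their bounds.

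For genes changed in both knockdowns, 20 simulated pairs of unchanged groups against the same controls gave the overlap and covariance where no gene changes. The alternatives tried were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, limma-voom, other scalings, filters and pseudocounts, no mean-variance trend, only the 2 groups compared, a replicate block, a fold threshold, and each library left out in turn. The last of these leaves 1 group with a lone library, which is assumed to vary like the others. These were fixed before the data were examined, except that the edgeR test on recovered reads with TMM, the pseudocounts, TMM scaling and the fit without a trend were added afterwards. So were DESeq2 size factors in the limma fit for genes, lists without a filter, and the shared count with only the 2 groups compared.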

Results

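Gene expression was measured by poly(A) RNA sequencing in 22RV1 prostate cancer cells that stably expressed shLuc, shIMPA1 or shIMPDH2, with 2 libraries per group. IMPA1 encodes inositol monophosphatase 1, which releases free inositol from inositol phosphates. IMPDH2 encodes the rate-limiting enzyme of guanine nucleotide synthesis, which converts IMP to XMP. Libraries held between 20828900 and 27773294 reads in the listed genes. The 10 most abundant genes of each library took between 4.19% and 5.23% of its reads. The first principal component carried 50.7% of the variance and the second 32.5%, and together they separated the 3 groups. The shIMPA1 libraries lay furthest apart: 934 genes differed more than 2-fold between them, against 266 between the shLuc and 398 between the shIMPDH2 libraries. Values are normalized read counts as mean ± SD, fold changes are on the log2(value + 1) scale, and adjusted p-values are from limma unless camera is named.

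Each hairpin lowered its own target moderately and left the other target without a call. IMPA1 (ENSG00000133731, protein coding, GRCh38 chromosome 8, 81657961 to 81686693) stood at 1476 ± 205 (SD, n = 2) in shLuc, 1029 ± 102 (SD, n = 2) in shIMPA1 and 1819 ± 33.3 (SD, n = 2) in shIMPDH2. It fell 1.43-fold in shIMPA1 (log2 fold change -0.52, SE 0.13, limma adjusted p = 0.0145), while in shIMPDH2 its log2 fold change was 0.31 (limma adjusted p = 0.140). IMPDH2 (ENSG00000178035, protein coding, GRCh38 chromosome 3, 49024325 to 49029408) stood at 4651 ± 539 (SD, n = 2) in shLuc, 3049 ± 166 (SD, n = 2) in shIMPDH2 and 4745 ± 439 (SD, n = 2) in shIMPA1. It fell 1.52-fold in shIMPDH2 (log2 fold change -0.61, SE 0.13, limma adjusted p = 0.00999), and its log2 fold change in shIMPA1 was 0.03 (limma adjusted p = 0.883). Both libraries of each knockdown lay below both shLuc libraries for the targeted gene. With only the 2 groups compared, the limma adjusted p was 0.0398 for IMPA1 and 5.47e-07 for IMPDH2. The IMPA1 call was lost without shLuc replicate 1 (log2 fold change -0.37, limma adjusted p = 0.159). The IMPDH2 call was lost without shLuc replicate 2 (-0.49, limma adjusted p = 0.127), shIMPDH2 replicate 1 (-0.55, 0.115) or shIMPDH2 replicate 2 (-0.66, 0.0787), and both calls were lost in a fit without a mean-variance trend (0.0671 for IMPA1 and 0.0612 for IMPDH2).

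**Figure D1:**
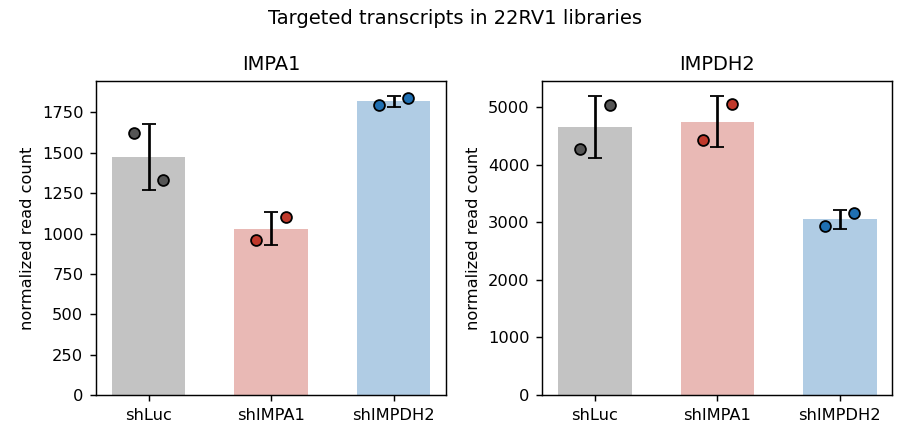
Normalized read counts of IMPA1 and IMPDH2 in the 6 libraries, with bars for group means, error bars for SD (n = 2) and points for single libraries. IMPA1 was lowest in shIMPA1 (1029) and IMPDH2 was lowest in shIMPDH2 (3049).

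The comparison of shIMPA1 with shLuc asked what differs in the transcriptome of cells with a moderately lowered IMPA1 transcript. With 1 stable line per group, effects of a hairpin or line beyond its target cannot be told apart. Of all genes tested, 30.2% were called in shIMPA1. In shIMPA1, 32 of 34 genes of DNA replication, 30 of 34 of mitosis and 21 of 24 of cholesterol synthesis fell, and 22 of 30 targets of the stress-induced transcription factor ATF4 rose. Each of these 4 lists passed camera with the preset correlation but not with an estimated one (adjusted p = 0.435, 0.550, 0.411 and 0.411). In the same order, their fry adjusted p was 0.0379, 0.150, 0.0146 and 0.0146. SLC7A8, a neutral amino acid transporter, rose 27.8-fold, from 203 ± 16.7 (SD, n = 2) to 5701 ± 990 (SD, n = 2). SUSD2, a membrane protein with a sushi domain (ENSG00000099994, GRCh38 chromosome 22, 24181259 to 24189110), fell 106-fold, from 8322 ± 1217 (SD, n = 2) to 77.5 ± 4.65 (SD, n = 2). The intermediate filament gene VIM (vimentin, ENSG00000026025, GRCh38 chromosome 10, 17228259 to 17237593) fell 16.5-fold, from 706 ± 67.5 (SD, n = 2) to 41.8 ± 1.94 (SD, n = 2).

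Besides SLC7A8, the largest rises in shIMPA1 were in TUNAR, a transcript first described in neural differentiation (log2 fold change 6.86, 1560 ± 93.3 against 12.4 ± 0.247, SD, n = 2), ANKRD33 (6.76), the cytochrome P450 gene CYP4F8 (6.31), the cadherin CDH26 (6.30) and the actin-binding SYNPO2 (5.80). They continued with the transcription cofactor LBH (5.41), the secreted matrix protein SMOC1 (5.08), the potassium channel subunit KCNG1 (4.95), the calcium-binding S100P (4.71), the monocarboxylate transporter SLC5A8 (4.44) and the homeobox gene HOXD8 (4.30). CDH26 differed widely between the shIMPA1 libraries, with a mean of 486 ± 468 (SD, n = 2). Among the falls, NUDT12, an NADH pyrophosphatase, had 0 reads in shIMPA1 and 341 in shLuc, at least 115-fold lower. DDX53, an RNA helicase gene of the germline, had a log2 fold change of -6.24, the monocarboxylate transporter family gene SLC16A14 of -5.97, the nuclear receptor RORB of -5.18 and the growth factor HGF of -5.01. CRISPLD1 (-4.67), the histamine-degrading enzyme HNMT (-4.49), the actin-bundling VIL1 (-4.31) and the focal adhesion gene TNS3 (-4.31) followed. ACTN2, a muscle actinin, had 3 reads in shIMPA1 and 92 in shLuc, a ratio of 30.9 (95% counting interval 10.3 to 153). The limma adjusted p was at most 0.00167 for each of these genes, and each kept its call in every fit without 1 library that tested it. DDX53 did not pass the filter without either shLuc library. The RORB fold rested on 1 library, with log2 fold changes of -3.21 without shIMPA1 replicate 2 and -7.16 without shIMPA1 replicate 1.

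Of 34 genes of the G1/S transition and DNA replication, 32 fell in shIMPA1, with a median log2 fold change of -1.26 (camera adjusted p = 1.28e-15, adjusted p = 0.435 with an estimated correlation). The replicative helicase subunits MCM3 (-1.47), MCM4 (-1.46) and MCM6 (-1.29) and the origin licensing factor CDC6 (-1.53) were among them. Of 34 genes of G2 and mitosis, 30 fell, with a median of -1.16 (camera adjusted p = 3.88e-11, adjusted p = 0.550 with an estimated correlation), including the mitotic kinesin KIF11 (-1.50), cyclin A2 (CCNA2, -1.50) and the mitotic kinase AURKB (-1.53). Adjusted over the list alone, 32 of the G1/S and 32 of the G2/M genes fell. The size of both changes depended on the shIMPA1 library, with G1/S medians of -0.82 without replicate 2 and -1.65 without replicate 1, and G2/M medians of -0.50 and -1.78. The same split moved CCNA2 (-0.98 and -2.02) and AURKB (-0.95 and -2.11).

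Among 30 ATF4 targets of the integrated stress response, 22 rose in shIMPA1 and 1 fell, the amino acid transporter SLC38A2 (chosen after its values were seen), with a median log2 fold change of 0.81 (camera adjusted p = 9.01e-10, adjusted p = 0.411 with an estimated correlation). Adjusted over the list alone, 23 rose and 1 fell. The transcription factor DDIT3 rose from 1712 ± 187 (SD, n = 2) to 10414 ± 1490 (SD, n = 2), a log2 fold change of 2.60. The mTORC1 inhibitor SESN2 (1.76), the pseudokinase TRIB3 (1.60) and the tryptophanyl-tRNA synthetase WARS1 (1.25) also rose. Heat shock genes went the other way: 12 of 14 fell (13 adjusted over the list alone), with a median of -0.86 (camera adjusted p = 2.80e-07, adjusted p = 0.411 with an estimated correlation). Examples were the chaperones HSPA1B (-1.10), HSPH1 (-0.93) and HSPB1 (-1.08) and the co-chaperone CHORDC1 (-1.13). Endoplasmic reticulum chaperones and unfolded protein response genes split, with 6 of 22 higher and 8 lower (6 and 9 adjusted over the list alone, camera adjusted p = 0.368). The folding genes MANF (-1.54), PDIA4 (-1.13) and SDF2L1 (-1.05) fell while the stress sensor ERN1 rose (1.58). Of 29 p53 targets, 6 rose and 5 fell (the same counts adjusted over the list alone, camera adjusted p = 0.399), and the stress-induced cytokine GDF15 (3.61), GADD45A (2.17), SESN2 and the death receptor TNFRSF10B (1.54) led the rises.

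Of 24 genes of cholesterol synthesis and uptake, 21 fell in shIMPA1 and 1 rose, the sterol reductase TM7SF2, chosen after its values were seen (21 and 1 adjusted over the list alone). The median log2 fold change was -1.10 (camera adjusted p = 1.61e-11, adjusted p = 0.411 with an estimated correlation). HMGCS1, which makes HMG-CoA for the mevalonate pathway, fell from 11380 ± 478 (SD, n = 2) to 2595 ± 631 (SD, n = 2), and the squalene epoxidase SQLE (-2.00), the sterol carrier STARD4 (-1.25) and mevalonate kinase MVK (-1.20) fell too. The fatty acid list had 3 of 20 genes higher and 8 lower (4 and 8 adjusted over the list alone, camera adjusted p = 0.281). Its members included the desaturase SCD (1.36) and the acyl-CoA synthetase ACSL1 (1.23) higher and the NADPH-producing malic enzyme ME1 (-2.17) and acetyl-CoA synthetase ACSS2 (-1.11) lower. All 13 mitochondrially encoded transcripts had negative fold changes, and 11 passed the test (13 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 1.59e-05, adjusted p = 0.550 with an estimated correlation). Fry did not call this list (fry adjusted p = 0.0590). The ATP synthase subunits MT-ATP8 and MT-ATP6 (both -0.98) lost their calls without shLuc replicate 2, at limma adjusted p = 0.0507 and 0.0531. Nuclear-encoded respiratory chain genes passed in 7 of 42 cases, with 1 higher and 6 lower (1 and 3 adjusted over the list alone, camera adjusted p = 0.599).

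Nucleotide and inositol enzymes, the pathways of the targets, changed in part. The G1/S list shares TYMS with the pyrimidine list and RRM2 with the guanine, adenine and salvage list, so these lists are not separate from it. Of 8 enzymes of de novo purine synthesis, 4 fell in shIMPA1 (4 adjusted over the list alone): the phosphoribosyl pyrophosphate synthetases PRPS1 (-1.11) and PRPS2 (-1.05), PAICS (-0.64) and PFAS (-0.78). The list median was -0.45 (camera adjusted p = 0.0154, adjusted p = 0.411 with an estimated correlation). PFAS lost its call without shLuc replicate 1 or 2 (limma adjusted p up to 0.132), with log2 fold changes of -0.36 without shIMPA1 replicate 2 and -1.20 without shIMPA1 replicate 1. Of 12 pyrimidine genes, 4 fell (4 adjusted over the list alone, fry adjusted p = 0.0724 for the list): thymidylate synthase TYMS (-1.21), thymidine kinase TK1 (-1.18), CMPK1 (-0.49) and the dUTPase DUT (-0.54). That list call (camera adjusted p = 0.0394, adjusted p = 0.525 with an estimated correlation) was lost without shLuc replicate 2 or shIMPA1 replicate 2, where the median was -0.16 at camera adjusted p = 0.139. TYMS lost its call without shLuc replicate 2 and TK1, CMPK1 and DUT without either shLuc library, at limma adjusted p of up to 0.105. Without shIMPA1 replicate 2, TYMS stood at -0.68 and TK1 at -0.65. In the guanine, adenine and salvage list 7 of 23 genes fell (7 adjusted over the list alone, camera adjusted p = 0.107), among them the salvage enzyme HPRT1 (-1.34) and the ribonucleotide reductase subunit RRM1 (-1.34). The inositol list had 5 of 26 genes higher and 7 lower (the same adjusted over the list alone, camera adjusted p = 0.599). The lower genes include IMPA1, the target of the hairpin. IMPA2, the second inositol monophosphatase, fell from 1203 ± 50.9 (SD, n = 2) to 584 ± 85.4 (SD, n = 2), a log2 fold change of -1.05.

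Markers of prostate identity and of stem cells moved both ways in shIMPA1. Of 29 androgen response genes, 8 rose and 5 fell (9 and 7 adjusted over the list alone, camera adjusted p = 0.601). The secreted phosphatase ACP3 (-1.69) fell, and the serine proteases KLK4 (1.30) and TMPRSS2 (1.55) rose. Of 21 stemness markers, 3 rose and 9 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.0743). The R-spondin receptor LGR4 (-1.33), the chemokine receptor CXCR4 (-2.29), the drug efflux pump ABCG2 (-1.61) and nestin (NES, -1.25) fell. The NES call was lost without shLuc replicate 2 (limma adjusted p = 0.0626), and its value was -0.73 without shIMPA1 replicate 2. Mesenchymal genes had 2 of 19 members higher and 8 lower (the same adjusted over the list alone, camera adjusted p = 0.0616), led by VIM, thrombospondin THBS1 (-2.14), the matricellular CCN2 (-2.79) and lysyl oxidase LOX (-1.73). Of 5 stromal markers, 3 fell (3 adjusted over the list alone, median -0.86, camera adjusted p = 0.0616), LUM (-2.55), the collagen gene COL3A1 (-2.21) and the smooth muscle actin ACTA2 (-0.86). COL3A1 lost its call without either shLuc library and ACTA2 without either shLuc library or shIMPA1 replicate 2, at limma adjusted p of up to 0.135 and 0.136. Without shIMPA1 replicate 1, COL3A1 stood at -1.39. Of 5 genes characteristic of other cell lines, 3 fell (3 adjusted over the list alone), at camera adjusted p = 0.00867 (adjusted p = 0.411 with an estimated correlation). They were VIM and the caveolins CAV1 (-2.60) and CAV2 (-1.55, lost without either shLuc library, limma adjusted p up to 0.120).

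In shIMPA1, 2479 genes rose and 2882 fell, of which 694 and 1227 changed more than 2-fold, and edgeR on the recovered reads called 5480. Leaving out 1 library moved this count of 5361 to 2189 without shLuc replicate 1, 2147 without shLuc replicate 2 and 7940 without shIMPA1 replicate 1. Of the 159 named genes called, 121 kept their call in every such fit that tested them.

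**Figure D2:**
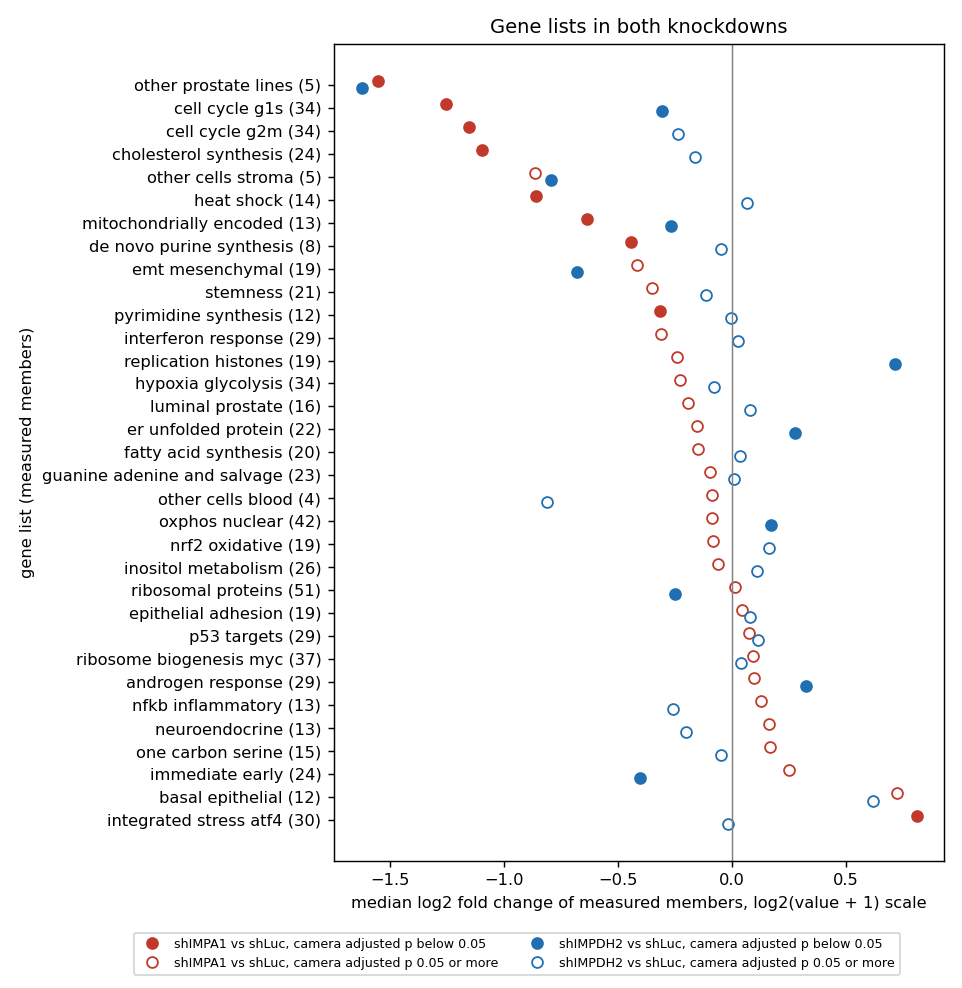
Median log2 fold change, on the log2(value + 1) scale, of the measured members of each of the 33 gene lists in shIMPA1 (red) and shIMPDH2 (blue) against shLuc, with filled points for a camera adjusted p below 0.05. The G1/S list lay at -1.26 in shIMPA1 and -0.31 in shIMPDH2, and the ATF4 list at 0.81 and -0.02.

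The comparison of shIMPDH2 with shLuc asked what differs in cells with a moderately lowered IMPDH2 transcript. Of all genes tested, 17.0% were called in shIMPDH2. In shIMPDH2, 10 of 29 androgen response genes and 6 of 19 replication-dependent histone transcripts rose, and 7 of 19 mesenchymal genes fell. Each of these 3 lists passed camera with the preset correlation but not with an estimated one (adjusted p = 0.255). In the same order, their fry adjusted p was 0.00227, 0.00262 and 0.00388. SLC45A3, a prostate transporter gene induced by androgen, rose from 580 ± 17.2 (SD, n = 2) to 2656 ± 117 (SD, n = 2). SLC5A6, the sodium-dependent multivitamin transporter, rose 8.67-fold, from 732 ± 61.3 (SD, n = 2) to 6345 ± 16.1 (SD, n = 2). SUSD2 fell 138-fold, to 59.2 ± 3.71 (SD, n = 2).

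The gap junction gene GJD2 had 532 reads in shIMPDH2 and 0 in shLuc, at least 228-fold higher. C9orf152 (log2 fold change 5.67), the Wnt-cleaving protease gene TRABD2B (5.15), the thyroid hormone-binding CRYM (3.66) and DLK2 (3.63) were among the next largest rises. They were followed by SLC5A6 (3.12), ANKRD33 (2.75), SYNPO2 (2.70), ANKRD29 (2.68), the tyrosine phosphatase PTPRR (2.62) and carbonic anhydrase CA12 (2.60). Among the falls, DDX53 had 1 read in shIMPDH2 and 469 in shLuc, a ratio of 365 (95% counting interval 65.2 to 14453). CDR1 (-4.88) and LINC00632 (-4.31) fell together, and LINC00632 overlaps CDR1 on the opposite strand, so their reads may not be separable. The interferon-induced IFITM1 (-4.13), CRISPLD1 (-3.98), the proteoglycan lumican (LUM, -3.80), the vasodilator peptide adrenomedullin (ADM, -3.67), neuromedin B (NMB, -3.66), the calcium channel subunit CACNG7 (-3.58), the glutamate transporter SLC17A6 (-3.50) and VIM (-3.40) followed. The limma adjusted p was at most 0.00936 for each of these genes, and all but ANKRD33 kept their call in every fit without 1 library that tested them. GJD2 did not pass the filter without either shIMPDH2 library, nor DDX53 without either shLuc library. ANKRD33 lost it without shLuc replicate 1 (1.67) or shIMPDH2 replicate 2 (2.43, limma adjusted p = 0.112).

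Of 29 androgen response genes, 10 rose in shIMPDH2 and 2 fell (12 and 3 adjusted over the list alone), with a median log2 fold change of 0.32 (camera adjusted p = 0.00314, adjusted p = 0.255 with an estimated correlation). SLC45A3 (2.19), TMPRSS2 (2.01), the glycine methyltransferase GNMT (1.76) and PMEPA1 (1.22), a brake on TGF-beta signalling, rose. Of 19 mesenchymal genes, 7 fell (10 adjusted over the list alone), with a median of -0.68 (camera adjusted p = 4.96e-05, adjusted p = 0.255 with an estimated correlation), among them THBS1 (-1.51), the collagen gene COL5A1 (-1.74), LOX (-1.64) and VIM. All 5 genes characteristic of other cell lines fell (5 adjusted over the list alone, median -1.62, camera adjusted p = 4.45e-05, adjusted p = 0.255 with an estimated correlation), with the neurofilament gene NEFL at -1.11. In that list CAV1 (-1.62) lost its call without either shLuc library and CAV2 (-2.07) without shLuc replicate 2, at limma adjusted p of up to 0.0732 and 0.0827.

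Replication-dependent histone genes, whose transcripts normally lack a poly(A) tail, rose in 6 of 19 cases (10 adjusted over the list alone), with a median log2 fold change of 0.72 (camera adjusted p = 0.000840, adjusted p = 0.255 with an estimated correlation). H2AC6 rose from 198 ± 6.45 (SD, n = 2) to 873 ± 26.2 (SD, n = 2), and H2BC12 (1.82), H2BC21 (1.46) and the linker histone H1-2 (1.23) rose with it. Endoplasmic reticulum genes rose in 5 of 22 cases (5 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.000316, adjusted p = 0.770 with an estimated correlation). Fry called neither this list (fry adjusted p = 0.132) nor the immediate early list described next (0.261). SEL1L (0.83), part of the machinery that removes misfolded proteins, kept its call without each library. Its partner HERPUD1 (0.82), the transcription factor XBP1 (0.59) and the co-chaperone DNAJB9 (0.99) lost theirs without shLuc replicate 1 or either shIMPDH2 library, and DNAJB9 also without shLuc replicate 2, with limma adjusted p of up to 0.158. Immediate early genes had 1 of 24 members higher and 7 lower (1 and 9 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 0.0144, adjusted p = 0.855 with an estimated correlation, and 0.0565 without shLuc replicate 2). JUNB (-0.64) and MYC (-0.65), both growth-induced transcription factors, lost their calls without shLuc replicate 1 or shIMPDH2 replicate 1, and MYC also without replicate 2 of either group, at limma adjusted p of up to 0.0945 for JUNB and 0.112 for MYC.

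A further 5 lists passed camera with the preset correlation in shIMPDH2, and fry called none of them. Their fry adjusted p was 0.452 for G1/S, 0.347 for ribosomal, 0.247 for respiratory chain, 0.365 for mitochondrial and 0.0735 for stromal genes. The G1/S list had a median log2 fold change of -0.31 with 2 of 34 genes lower (1 adjusted over the list alone), at camera adjusted p = 0.00913 (adjusted p = 0.871 with an estimated correlation, and 0.0559 without shIMPDH2 replicate 1). These were MCM3 (-1.70) and GINS1 (-0.80, lost without any 1 shLuc or shIMPDH2 library, limma adjusted p up to 0.206). Ribosomal proteins had a median of -0.25 with 3 of 51 lower (camera adjusted p = 0.000478, adjusted p = 0.855 with an estimated correlation, and 0.0733 without shIMPDH2 replicate 1, where the median was -0.16, as it was without shLuc replicate 1). Nuclear respiratory chain genes had a median of 0.17 with 3 of 42 higher (camera adjusted p = 0.00312, adjusted p = 0.855 with an estimated correlation, and 0.131 without shIMPDH2 replicate 2, where the median was 0.09, against 0.27 without shIMPDH2 replicate 1). Adjusted over the list alone, none of the ribosomal or respiratory chain genes passed in limma. The mitochondrially encoded transcripts had 0 genes called by limma, edgeR or voom, 3 called by DESeq2 and 4 of 13 at an unadjusted p under 0.05. Their median was -0.27 (camera adjusted p = 0.0275, adjusted p = 0.855 with an estimated correlation, and 0.238 without shIMPDH2 replicate 2, where the median was -0.18). Stromal markers fell in 2 of 5 cases (2 adjusted over the list alone, median -0.80), at camera adjusted p = 0.0293 (adjusted p = 0.582 with an estimated correlation, and 0.0621 without shIMPDH2 replicate 1). They were LUM and the collagen gene COL1A1 (-0.80, lost without any 1 shLuc or shIMPDH2 library, limma adjusted p up to 0.151). The calls of the G1/S, respiratory chain and mitochondrial lists were also lost without shLuc replicate 2, that of the mitochondrial list without either shIMPA1 library, and that of the stromal list without shLuc replicate 1.

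In shIMPDH2, where 17.0% of all genes tested were called, the guanine, adenine and salvage list held calls and the inositol list held none. In the guanine, adenine and salvage list 3 of 23 genes rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.895): GMP reductase GMPR (1.19) and guanylate kinase GUK1 (0.61) rose and IMPDH2 and adenosine deaminase ADA (-0.71) fell. GMPR, GUK1 and ADA lost their calls without either shIMPDH2 library, GMPR and ADA also without shLuc replicate 1, and GUK1 and ADA also without shLuc replicate 2, at limma adjusted p of up to 0.135 (GMPR), 0.161 (GUK1) and 0.187 (ADA). None of the 26 inositol genes passed in limma, edgeR, DESeq2 or voom, with 7 at an unadjusted p under 0.05 (camera adjusted p = 0.541). None of the 8 de novo purine genes passed in limma or these other tools, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.732). Among 34 G2/M genes limma and DESeq2 called none, edgeR and voom called 1 each, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.104). These tools all took the spread from all 6 libraries, the wider shIMPA1 pair included. With only the 2 groups compared, limma called 6382 genes against 3018, and these lists were not counted in that fit. A missing call here therefore does not show a lack of change. Of 30 ATF4 targets, 3 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.841), and of 24 cholesterol genes 1 rose and 3 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.334). Of 21 stemness markers, 2 rose and 4 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.534), with the adhesion receptor CD44 (0.98) higher and MYC, CXCR4 (-1.38) and the pluripotency factor SOX2 (-1.34) lower. These 4 genes lost their calls without either shLuc library and without shIMPDH2 replicate 2, and all but CXCR4 without shIMPDH2 replicate 1, with limma adjusted p of up to 0.121 (CD44), 0.112 (MYC), 0.161 (CXCR4) and 0.163 (SOX2).

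In total, 1395 genes rose and 1623 fell in shIMPDH2, of which 349 and 815 changed more than 2-fold, and edgeR on the recovered reads called 3007. The count of 3018 rested on the libraries and groups in the fit. It was 803 and 773 without shLuc replicate 1 and 2, and 998 and 839 without shIMPDH2 replicate 1 and 2. It was 6383 and 6386 without shIMPA1 replicate 1 and 2, and 6382 with the shIMPA1 libraries left out together. Of the 124 named genes called, 60 kept their call in every fit without 1 library that tested them.

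Setting shIMPDH2 directly against shIMPA1 tested which responses differed between the knockdowns. ACTN2 had 399 reads in shIMPDH2 and 3 in shIMPA1, a ratio of 172 (95% counting interval 58.5 to 839), GJD2 was at least 230-fold higher in shIMPDH2 and NUDT12 at least 37.7-fold higher. HGF (log2 fold change 5.06), SLC16A14 (4.64) and HNMT (3.74) were higher in shIMPDH2. HOXD8 (-5.95), CACNG7 (-5.42), the chemerin receptor CMKLR2 (-4.85), SLC7A8 (-4.65), TUNAR (-4.56) and the calcium channel CACNA1H (-4.43) were lower, each with a limma adjusted p of at most 0.000257.

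By camera with the preset correlation, the cell cycle, cholesterol, heat shock and ATF4 lists differed between the knockdowns. Fry called the cholesterol (fry adjusted p = 0.0162), heat shock (0.00926) and ATF4 lists (0.0156), but not G1/S (0.0785) or G2/M (0.235). In shIMPDH2 relative to shIMPA1, 26 of 34 G1/S genes were higher (29 adjusted over the list alone, median 0.84, camera adjusted p = 2.44e-11, adjusted p = 0.467 with an estimated correlation), among them CDC6 (1.44) and MCM4 (1.37). So were 17 of 34 G2/M genes (25 adjusted over the list alone, median 0.81, camera adjusted p = 9.81e-09, adjusted p = 0.467 with an estimated correlation). Their medians were 0.46 and 0.25 without shIMPA1 replicate 2, and 1.30 and 1.42 without shIMPA1 replicate 1. Cholesterol genes were higher in 19 of 24 cases (20 adjusted over the list alone, median 0.81, camera adjusted p = 2.53e-11, adjusted p = 0.367 with an estimated correlation), with HMGCS1 at 1.61. Heat shock genes were higher in 9 of 14 cases (11 adjusted over the list alone, median 0.77, camera adjusted p = 2.08e-06, adjusted p = 0.332 with an estimated correlation). Endoplasmic reticulum genes were higher in 13 of 22 cases and lower in 1 (13 and 2 adjusted over the list alone, camera adjusted p = 7.22e-05, adjusted p = 0.467 with an estimated correlation), MANF at 1.74 and ERN1 at -1.70. ATF4 targets were lower in 22 of 30 cases and higher in 1 (23 and 2 adjusted over the list alone, median -0.86, camera adjusted p = 1.17e-10, adjusted p = 0.332 with an estimated correlation), with DDIT3 at -2.04. Replication histones were higher in 10 of 19 cases (11 adjusted over the list alone, median 0.85, camera adjusted p = 3.29e-05, adjusted p = 0.332 with an estimated correlation).

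Prostate identity genes differed too. Luminal markers were higher in shIMPDH2 than in shIMPA1 in 9 of 16 cases and lower in 1 (median 0.62, camera adjusted p = 0.00233, adjusted p = 0.332 with an estimated correlation). The counts were the same adjusted over the list alone, and the higher genes included the keratin KRT19 (1.64), the folate hydrolase FOLH1 (1.60) and ACP3 (2.01). Androgen response genes were higher in 11 of 29 cases and lower in 3 (12 and 4 adjusted over the list alone), at camera adjusted p = 0.0236 (adjusted p = 0.332 with an estimated correlation), led by SLC45A3 (2.73). Their median of 0.27 was 0.13 without shIMPA1 replicate 1 and 0.46 without shIMPA1 replicate 2. Immediate early genes were lower in 9 of 24 cases (10 adjusted over the list alone, camera adjusted p = 3.29e-05, adjusted p = 0.467 with an estimated correlation, fry adjusted p = 0.0591), with the phosphatase DUSP4 at -2.36, IER3 at -2.57 and EGR3 at -1.95. Their median of -0.39 was -0.22 without shIMPA1 replicate 1 and -0.71 without shIMPA1 replicate 2, and the luminal median was 0.41 without shIMPA1 replicate 2. For stemness markers the difference between the knockdowns did not pass (camera adjusted p = 0.0710), with 5 of 21 genes higher and 3 lower (7 and 3 adjusted over the list alone), among them SOX9 (1.45), LGR4 (1.21) and SOX2 (-2.57).

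Several metabolic lists and the interferon list were higher in shIMPDH2 than in shIMPA1 by camera with the preset correlation. Fry called the de novo purine, guanine and adenine, and interferon lists (fry adjusted p = 0.00926 each) and the NRF2 list (0.0156). It did not call the respiratory chain (0.104), mitochondrial (0.155), pyrimidine (0.0989) or fatty acid list (0.0591). The inositol list (camera adjusted p = 0.251), the serine and folate list (0.526) and the glycolysis and hypoxia list (0.195) did not pass. De novo purine enzymes were higher in 3 of 8 cases, PRPS1 (0.94) and PAICS (0.76) among them (camera adjusted p = 0.00925, adjusted p = 0.332 with an estimated correlation), with a median of 0.30, or 0.52 without shIMPA1 replicate 1. Guanine, adenine and salvage genes were higher in 9 of 23 cases and lower in 3, the hairpin target IMPDH2 among the lower (camera adjusted p = 0.0269, adjusted p = 0.332 with an estimated correlation). Interferon genes were higher in 9 of 29 cases and lower in 3 (camera adjusted p = 0.0176, adjusted p = 0.332 with an estimated correlation). Nuclear respiratory chain genes were higher in 11 of 42 cases (camera adjusted p = 0.00233, adjusted p = 0.494 with an estimated correlation, and 0.138 without shIMPA1 replicate 1), with a median of 0.26, or 0.17 without shIMPDH2 replicate 2. Mitochondrially encoded transcripts were higher in 3 of 13 cases (camera adjusted p = 0.00460, adjusted p = 0.516 with an estimated correlation, and 0.295 without shIMPA1 replicate 2, where the median of 0.43 became 0.20). Pyrimidine genes were higher in 6 of 12 cases (camera adjusted p = 0.0269, adjusted p = 0.467 with an estimated correlation, and 0.199 without shIMPA1 replicate 2), with a median of 0.39, or 0.64 without shIMPA1 replicate 1. Oxidative stress genes driven by NRF2 were higher in 7 of 19 cases and lower in 2 (camera adjusted p = 0.00925, adjusted p = 0.332 with an estimated correlation, and 0.212 without shIMPA1 replicate 1). Fatty acid genes were higher in 7 of 20 cases and lower in 1 (camera adjusted p = 0.0297, adjusted p = 0.494 with an estimated correlation, and 0.0521 without shIMPDH2 replicate 1), with a median of 0.22, or 0.07 without shIMPA1 replicate 2.

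Ribosomal proteins and inflammatory genes lay lower in shIMPDH2 than in shIMPA1 as lists by camera with the preset correlation. Fry called the inflammatory list (fry adjusted p = 0.00926) but not the ribosomal list (0.341). Inflammatory NF-kappaB targets were lower in 4 of 13 cases (camera adjusted p = 0.0269, adjusted p = 0.332 with an estimated correlation, and 0.0809 without shIMPA1 replicate 1). Ribosomal proteins had a median of -0.25 with 2 of 51 higher and 3 lower (camera adjusted p = 0.0148, adjusted p = 0.736 with an estimated correlation). That median was -0.10 at 0.701 without shIMPA1 replicate 2, -0.16 at 0.271 without shIMPDH2 replicate 1, and -0.42 without shIMPA1 replicate 1. Adjusted over the list alone, the genes higher and lower were 3 and 0 for de novo purines, 10 and 3 for guanine and adenine, 9 and 3 for interferon, 11 and 0 for the respiratory chain and 3 and 0 for mitochondrial transcripts. They were 6 and 2 for pyrimidines, 9 and 2 for NRF2, 8 and 1 for fatty acids, 0 and 4 for NF-kappaB and 0 and 0 for ribosomal proteins.

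Between the knockdowns, 2395 genes were higher and 2232 lower in shIMPDH2 (26.1% of genes tested), and edgeR on the recovered reads called 4550. The count of 4627 was 7052 without shIMPA1 replicate 1, and 1875 and 1430 without shIMPDH2 replicate 1 and 2. Of the 143 named genes called, 97 kept the call in every such fit that tested them.

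Both knockdowns also changed many genes in the same direction. SUSD2, VIM, ADM, CRISPLD1, NMB, DDX53, SLC17A6 and IFITM1 fell in both. So did the summed CPM of 5 genes characteristic of other cell lines, VIM among them (65.3 and 72.1 in the shLuc libraries, 38.5 and 30.5 in shIMPA1, 19.6 and 19.3 in shIMPDH2), and of 6 stromal markers, LUM among them (24.8 and 26.0, 19.3 and 13.6, 12.1 and 11.5). Because these sums include VIM and LUM, already named among the falls, they do not by themselves show a fall across the markers. C9orf152 (log2 fold change 3.49 in shIMPA1 and 5.67 in shIMPDH2), the blood coagulation initiator F3 (3.28 and 2.47), the oxidase AOX1 (3.14 and 2.41), ANKRD29 (3.90 and 2.68), SYNPO2, ANKRD33 and CDH26 rose in both. CDH26 (2.55 in shIMPDH2) lost its shIMPDH2 call without any 1 shLuc or shIMPDH2 library (limma adjusted p up to 0.140), and ANKRD33 without shLuc replicate 1 or shIMPDH2 replicate 2 (up to 0.112). ADM stood at 1696 ± 66.6 (SD, n = 2) in shLuc, 131 ± 14.2 (SD, n = 2) in shIMPA1 and 132 ± 10.4 (SD, n = 2) in shIMPDH2.

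In all, 652 genes rose and 795 fell in both knockdowns, where independent lists of these sizes would share 195 and 264. Of the 1577 genes called in both, 91.8% changed in the same direction. Because both comparisons use the same shLuc libraries, their chance values are shared: simulated unchanged groups gave a correlation of 0.487 between fold changes across genes, against 0.535 observed, but a covariance of 0.0313, against 0.249 observed, a difference of 0.218. Genes are not independent replicates, and part of the excess may come from the shared controls, which are too few to split. The shared count of 1447 was 364 and 341 without shLuc replicate 1 and 2, 541 and 497 without shIMPDH2 replicate 1 and 2, and 3356 and 2395 without shIMPA1 replicate 1 and 2.

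**Figure D3:**
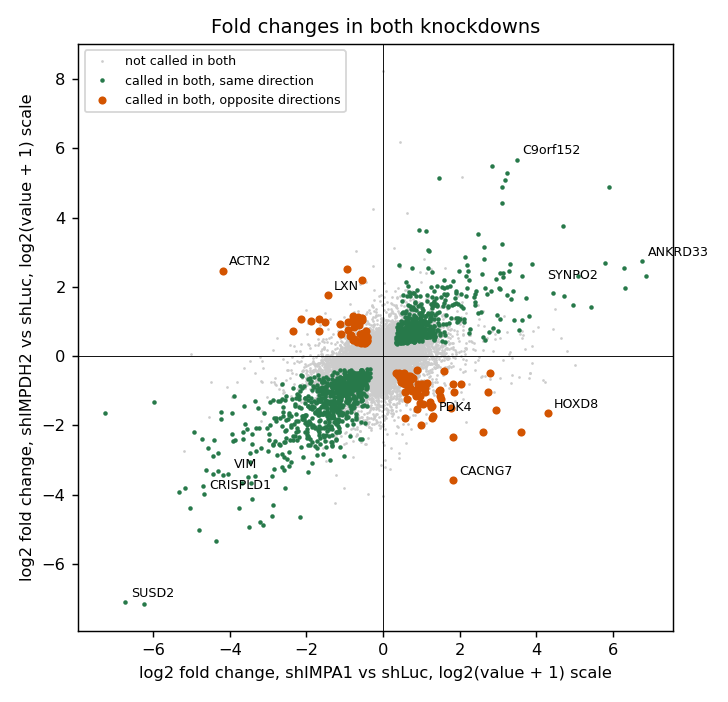
Log2 fold change of each gene in shIMPDH2 against shLuc (vertical axis) and in shIMPA1 against shLuc (horizontal axis), on the log2(value + 1) scale, with genes called in both in green (1447, same direction) or orange (130, opposite directions). SUSD2 lay at -6.72 and -7.10, and PDK4 at 1.31 in shIMPA1 and -1.74 in shIMPDH2.

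A smaller set of 130 genes changed in opposite directions, 71 up in shIMPA1 and down in shIMPDH2 and 59 the reverse. The difference between the knockdowns was called for all of them, as follows from this choice of genes. PDK4, a kinase that restrains pyruvate oxidation (ENSG00000004799, GRCh38 chromosome 7, 95583499 to 95596491), stood at 12566 ± 1315 (SD, n = 2) in shLuc, 31117 ± 3307 (SD, n = 2) in shIMPA1 and 3750 ± 93.5 (SD, n = 2) in shIMPDH2. ACTN2 (30.9 times lower in shIMPA1, 95% counting interval 10.3 to 153, and log2 fold change 2.47 in shIMPDH2), the carboxypeptidase inhibitor LXN (-1.44 and 1.76) and the purinergic receptor P2RY1 (-2.15 and 1.08) went the other way, and these and PDK4 kept both calls without any 1 library. CACNG7 (1.83 and -3.58) lost its shIMPA1 call without shLuc replicate 2 (limma adjusted p = 0.0566). HOXD8 (4.30 and -1.65) lost its shIMPDH2 call without shLuc replicate 1 or shIMPDH2 replicate 2 (up to 0.105), and the neuropilin NRP2 (1.76 and -1.50) without shLuc replicate 2 (0.0753). The glucose transporter SLC2A10 (-1.67 and 1.07) and the serine protease PRSS21 (-1.88 and 1.01) lost their shIMPDH2 calls without any 1 shLuc or shIMPDH2 library, at limma adjusted p of up to 0.260 and 0.123. The immune ligand ULBP1 (1.29 and -1.45) lost its shIMPDH2 call without the same libraries (up to 0.125) and its shIMPA1 call without either shLuc library or shIMPA1 replicate 1, where it stood at 0.76 (up to 0.106).

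The basal keratins KRT5, KRT14 and KRT6A, SFTPA2 and the luminal marker MSMB held reads mostly in 3 libraries. These 5 genes were chosen after their values were seen. No other gene, other basal keratins included, had at least 10 reads in each of these libraries and at most 3 in the others together. KRT5, KRT14 and KRT6A, keratins of basal epithelium, and SFTPA2, a lung surfactant protein gene, together had 1 and 3 reads in the shLuc libraries, 6 and 231 in the shIMPA1 libraries, and 164 and 164 in the shIMPDH2 libraries. MSMB, a protein secreted by luminal prostate cells, had 0 and 0, 3 and 15, and 36 and 42 reads. Of 12 basal genes, 4 rose and 1 fell in shIMPA1 and 5 rose and 2 fell in shIMPDH2 (the same adjusted over the list alone), at camera adjusted p = 0.385 and 0.206. Of 16 luminal genes, 2 rose and 7 fell in shIMPA1 and 5 rose and 4 fell in shIMPDH2 (the same adjusted over the list alone), at camera adjusted p = 0.0616 and 0.464. The anterior gradient protein AGR2 fell in both knockdowns (-2.42 and -1.72) and the keratin KRT19 rose in shIMPDH2 (1.09).

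**Figure D4:**
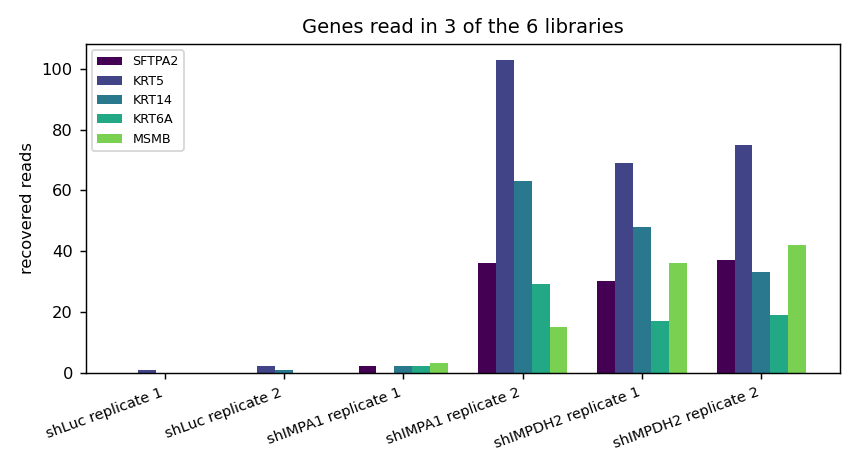
Reads of KRT5, KRT14, KRT6A, SFTPA2 and MSMB in each of the 6 libraries. The reads sat in shIMPA1 replicate 2 and both shIMPDH2 libraries, with 103 KRT5 reads in shIMPA1 replicate 2 and 0 in shIMPA1 replicate 1.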

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

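In 130 genes the knockdowns moved expression in opposite directions from shLuc. They were singled out because the groups differed, so the limma call of the difference between the knockdowns follows from this choice and adds no support. PDK4, for example, stood at 31117 ± 3307 (SD, n = 2) in shIMPA1 and 3750 ± 93.5 (SD, n = 2) in shIMPDH2.

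Each test below was chosen only after the result it concerns was seen. Both knockdowns changed 1447 genes in the same direction, SUSD2 and VIM among them. Simulated unchanged groups that shared the shLuc libraries gave at most 1 such gene. Adjusted calls are rare by design where no gene changes, so that count cannot tell how many shared calls the common controls added. The covariance of fold changes, which rests on no call, was 0.0313 in the simulations against 0.249 observed. This argues against shared chance alone, though genes were simulated independently. A difference of the single shLuc line from the cells it came from might also appear as a change common to both knockdowns. Of the shared genes, 22.25% also differed between the knockdowns, against 26.1% of all genes, and this cannot separate such a difference from a common effect of both knockdowns. A second control line would be needed.

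Reads of KRT5, KRT14, KRT6A and SFTPA2 sat in shIMPA1 replicate 2 and both shIMPDH2 libraries. Tests of their ratio to each other (Monte Carlo permutation p = 0.4021) and of MSMB to them (permutation p = 1e-05, the smallest that 100000 resamples can give) allow for counting error alone. With 1 such library in shIMPA1, the spread between libraries is unknown, so reads from outside these cells cannot be told apart from expression by them, for the 4 genes or for MSMB. The limma adjusted p of KRT14 in shIMPDH2 was 0.00782 (up to 0.103 without any 1 shLuc or shIMPDH2 library).

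The shIMPA1 libraries lay further apart than those of the other groups, with the mitotic kinesin KIF11 at -1.01 without replicate 2 and -2.00 without replicate 1. Of the genes changed in shIMPA1, 77.17% lay further from shLuc in replicate 2 than in replicate 1 (57.2% for shIMPDH2), consistent with a stronger form of the same response for most genes. Some lists did not follow: in replicates 1 and 2 the medians were 1.08 and 0.71 for ATF4 targets, 0.43 and -0.08 for immediate early genes, and -0.90 and -0.90 for heat shock genes. The log2 ratio of IMPA1 in replicate 2 over replicate 1 was 0.2025, within the gap of 0.284 between the shLuc libraries, so a different depth of knockdown was neither shown nor excluded. Transcript length and GC content took up 1.311% of the variance of the difference between the shIMPA1 libraries, where 48.8% lay beyond that in shIMPDH2, which argues against a length or GC trend.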

How the results depend on the processing

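No gene or list called with all 6 libraries changed sign under any setting, and the numbers of genes changed stayed within 1.5 times under edgeR, DESeq2, voom, other scalings, filters and pseudocounts. With a replicate block, although the replicate numbers do not pair, they were 5298, 2939 and 4537 for shIMPA1, shIMPDH2 and between the knockdowns. Only genes beyond 2-fold left 1921, 1164, 1501 and 516 shared, by construction. Without a mean-variance trend, tried after the data were seen, the counts were 3508, 1727, 2909 and 820 shared, and neither IMPA1 (-0.52) nor IMPDH2 (-0.61) was called. With only the 2 groups compared, shIMPDH2 against shLuc gave 6382. Without each library in turn, the counts ranged from 2147 to 7940 for shIMPA1, 773 to 6386 for shIMPDH2, 1430 to 7052 between the knockdowns and 341 to 3356 shared. IMPA1 ranged from -0.66 to -0.37 and IMPDH2 from -0.72 to -0.49. SLC17A6 between the knockdowns, 0.04 and without a call, reversed to a called -0.80 without shIMPA1 replicate 2 (adjusted p = 0.042 in limma), and was 0.88 without shIMPA1 replicate 1. Lists called numbered 9, 11 and 20, with camera and an estimated correlation 0, 0 and 0, with fry 16, 6 and 17, and without each library 9 to 14, 7 to 12 and 18 to 20. Except where stated, the cause was not tested. Over all named genes and settings, 8497 values kept their side of the threshold, 515 lost a call and 145 gained one, and for lists these were 1234, 80 and 45. Few reads limit genes such as KRT6A, whose fold is only a lower bound.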

Other observations

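Glycolysis and hypoxia genes moved both ways in the knockdowns. ADM, the lactate exporter SLC16A3 (-1.49 in shIMPA1 and -1.45 in shIMPDH2) and the glycolytic kinase PFKP (-1.71 and -1.57) fell in both, while the growth factor VEGFA rose in shIMPA1 (1.13) and CA12 rose in shIMPDH2 (2.60). Of 34 such genes, 6 rose and 13 fell in shIMPA1 (camera adjusted p = 0.0704) and 5 rose and 6 fell in shIMPDH2 (camera adjusted p = 0.534). Neuroendocrine markers split: the secretory granule protein CHGA rose in shIMPA1 (1.08) and fell in shIMPDH2 (-1.02), and the Notch ligand DLL3 fell in shIMPDH2 (-1.22). As a list, 4 of 13 rose and 3 fell in shIMPA1 (camera adjusted p = 0.666), and 1 rose and 5 fell in shIMPDH2 (camera adjusted p = 0.105). Among immediate early genes the phosphatase DUSP4 (1.99) and IER3 (2.13) rose in shIMPA1, where 5 of 24 rose and 1 fell (camera adjusted p = 0.0616).

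Interferon genes fell in 9 of 29 cases and rose in 2 in shIMPA1 (camera adjusted p = 0.0502), with CMPK2 at -1.91 and the exonuclease ISG20 at 1.63. In shIMPDH2, 2 rose and 3 fell (camera adjusted p = 0.895), with a median of 0.03 but a mean of -0.07. Serine and folate genes had 3 of 15 higher and 4 lower in shIMPA1 (camera adjusted p = 0.761, median 0.17, mean -0.03) and 2 higher in shIMPDH2 (camera adjusted p = 0.558, median -0.05, mean 0.13), where the serine synthesis enzyme PSPH rose (1.90). Of 19 NRF2 targets, 5 rose and 5 fell in shIMPA1 (camera adjusted p = 0.599) and 4 rose and 1 fell in shIMPDH2 (camera adjusted p = 0.151), with the aldo-keto reductase AKR1C3 at -3.10 in shIMPA1. None of 13 NF-kappaB targets was called in shIMPDH2 by limma, edgeR, DESeq2 or voom, each with the spread of all 6 libraries. In shIMPDH2, 2 had an unadjusted limma p under 0.05 (camera adjusted p = 0.151), and in shIMPA1 3 rose (camera adjusted p = 0.385). Ribosome biogenesis genes had 8 of 37 higher and 4 lower in shIMPA1 (camera adjusted p = 0.427) and 1 lower in shIMPDH2 (camera adjusted p = 0.841).

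The authors' deposited table carries fold changes for a comparison its header does not name. In it, 617 genes had an adjusted p under 0.05, of which 370 rose and 247 fell. Over 13745 genes its fold changes correlated at 0.934 with the mean of both knockdowns against shLuc, at 0.817 with shIMPA1 alone and at 0.816 with shIMPDH2 alone.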
